A study of Mus musculus with 4 samples.

How the data were processed

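Gene expression in the urinary bladders of female C57BL/6 mice was measured on 1-colour arrays, 2 from control mice and 2 from mice given 50 ppm arsenic in the drinking water for 2 weeks. Per the labels' protocols, RNA was extracted with Trizol, checked for purity and integrity, amplified and labelled with Cy5. Scanner software, background correction and normalization are not given in the sources used here. The deposited table holds 1 intensity per probe and array on a linear scale, as read from its values: they run from below 0 to 385459, and values below 0 arise only where a background has been subtracted. On each array the deposited intensity values under 2000 steps were whole multiples of a single step (0.995 and 1.01 on the control arrays, 0.958 and 1.05 on the arsenic arrays; 100% whole within 0.02 of a step). The mean of the reciprocal steps was 1 within each group, so the factors look to have been set within each group, and the groups were not brought to a common scale by them. No batch, slide or scan date was given in the sources used here. The labels give 2 mice per group, and nothing ties each array to a mouse, so p-values measure the spread between these arrays, which may be technical. Factors set within each group could narrow that spread and make p-values too small. With the factors undone, 50 genes were called in place of 231.

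The table holds 26423 probes. The platform annotation paired 21876 of them with 1 gene name, 0 with several and 4547 with none, and 21825 could be looked up by gene ID in a mouse RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. The build behind the array's annotation is not given in the sources used here, so that table served only for names and no coordinates are printed. Where a gene had several probes (2424 of 19084 genes), the probe with the highest mean over all 4 arrays was used. Values at or below 0 were set to the lowest positive value, 0.958, and all values were taken to log2. The deposited scaling was kept and no filter on dim genes was set. No gene past the threshold had an array value at or below 0. The median standard error of a gene's difference was 0.062 (log2) in the brighter 50% of genes and 0.25 in the dimmest 25%. The arrays' number limits the precision.

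The arsenic and control arrays were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided), with 2 residual and 2.61 prior degrees of freedom and Benjamini-Hochberg adjustment. Gene lists were tested with camera at a preset correlation of 0.01, with the adjustment over 46 lists of at least 5 measured members. The list of immunoglobulin genes had 1 measured member and was not tested. Camera with an estimated correlation and fry were run beside it, and members were counted at an adjusted p under 0.05 over all genes and over the list alone. With an estimated correlation, camera rests on the 2 residual degrees of freedom, which leaves it little power over 46 lists. As a description, each list's median was set against 10000 random lists drawn from the 200 genes nearest in mean brightness to each member, with the 2.5th and 97.5th percentiles as the matched range; this step was added after the trend with brightness was seen.

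Genes named were, among those past the threshold with non-overlapping groups and a brighter group above the median of all genes, the 12 largest rises and the 12 largest falls, with predicted genes and olfactory receptors not named. Up to 4 members of each list with the smallest p, and 10 genes in every case (Hmox1, Nqo1, Gclc, Mt1, Mt2, As3mt, Cdkn1a, Mki67, Krt5 and Upk2), could be named too. Groups, tests, lists, this rule and 14 alternatives were fixed before the data were examined. The lists fixed as main results were NRF2 targets, metallothioneins, heat shock proteins, cell cycle, and luminal and basal urothelium. All other lists were fixed as context. The alternatives were median centring, quantile normalization, dropping the dimmest 25% or 50% of genes, an offset of 32, the mean of a gene's probes, all probes tested, eBayes without trend or with robust estimation, the replicate number as a block, leaving out each array, other thresholds, and the other list tests. Cyclic loess and undoing the scale factors were added after the data were seen. The steps were tested on simulated data for the comparison of arsenic with control, 10 simulations of 19084 genes with 200 changed in each. They found 52.2% of 1.5-fold, 86% of 2-fold, 98.6% of 4-fold and 99.2% of 8-fold changes, and 5.25% of calls were false. With nothing changed, 0 genes and 0 lists were called, and a list shifted by 0.25 (log2) was called in 10 of 10 simulations. The simulated noise was independent between genes and arrays, with no brightness trend, group scaling or replicate effect. The 200 changed genes were all brighter than the median. These rates therefore need not hold for the real arrays.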

Results

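Total RNA from the urinary bladders of female C57BL/6 mice, an inbred laboratory strain, was labelled with the dye Cy5 and measured on 1-colour arrays, each of which holds 1 sample. The control group had 2 arrays from mice that drank RO water, and the arsenic group had 2 arrays from mice that drank RO water with 50 ppm arsenic for 2 weeks. The question was which bladder genes and pathways differ in expression after this exposure. The intensities of all probes summed to 60012053 and 60810045 on the control arrays and to 63972482 and 63487396 on the arsenic arrays, with medians of 321, 320, 337 and 323. The number of arrays limits the precision of every value. Over the brighter 50% of genes, the correlation across genes was 0.989 between the control arrays, 0.987 between the arsenic arrays, and 0.978 to 0.988 between arrays of different groups. The median absolute log2 difference between arrays was 0.073 within the control group, 0.068 within the arsenic group and 0.12 to 0.16 between groups.

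Of the gene lists fixed as main results, NRF2 targets and glutathione or thioredoxin enzymes passed the gene list test camera upward. Cell cycle and mitosis passed it downward. Metallothioneins, heat shock proteins, and luminal and basal urothelium did not pass. In lists fixed as context, 7 of 23 immediate early genes rose with arsenic and 1 fell, and 5 of 15 glucocorticoid-responsive genes rose. Of 20 skeletal muscle genes 4 fell, as did 2 of 19 smooth muscle genes and 2 of 44 collagen genes. These context lists passed camera too. With an estimated correlation, each list named here that passed had a camera adjusted p = 0.492. Fosb and Fos, subunits of the AP-1 transcription factor, rose 5.01-fold and 4.59-fold. Rnu11, an RNA of the minor spliceosome, rose 6.75-fold, and Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, rose 6.59-fold. Myh2, a fast myosin heavy chain of skeletal muscle, was 7.81-fold lower, and Ankrd1, a muscle protein induced by stretch, was 5.85-fold lower. Of 19084 genes tested with limma, 231 changed at a Benjamini-Hochberg adjusted p under 0.05, 143 of them higher and 88 lower with arsenic. Their median size was 1.50-fold for rises and 1.64-fold for falls, and 43 changed by at least 2-fold, 18 up and 25 down. The split between higher and lower calls depended on scaling: quantile normalization gave 61 higher and 117 lower, median centring 34 and 51, cyclic loess 85 and 140, and undoing the deposited scale factors 23 and 27. It also depended on the filter, fit and threshold. Dropping the dimmest 25% of genes gave 376 higher and 157 lower, and dropping 50% gave 763 and 198. Limma without a trend gave 6 higher and 53 lower, and with robust estimation 631 and 257. An unadjusted p under 0.05 with at least 2-fold gave 22 and 339. With the replicate number as a block the split was 1706 and 515, though the labels give no origin for the numbers. Without control replicate 1 or without control replicate 2, limma called 0 genes at an adjusted p under 0.05 (2661 and 3207 at an unadjusted p under 0.05), while without arsenic replicate 1 it called 219 (79 higher, 140 lower) and without arsenic replicate 2 it called 38 (15, 23).

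**Figure D1:**
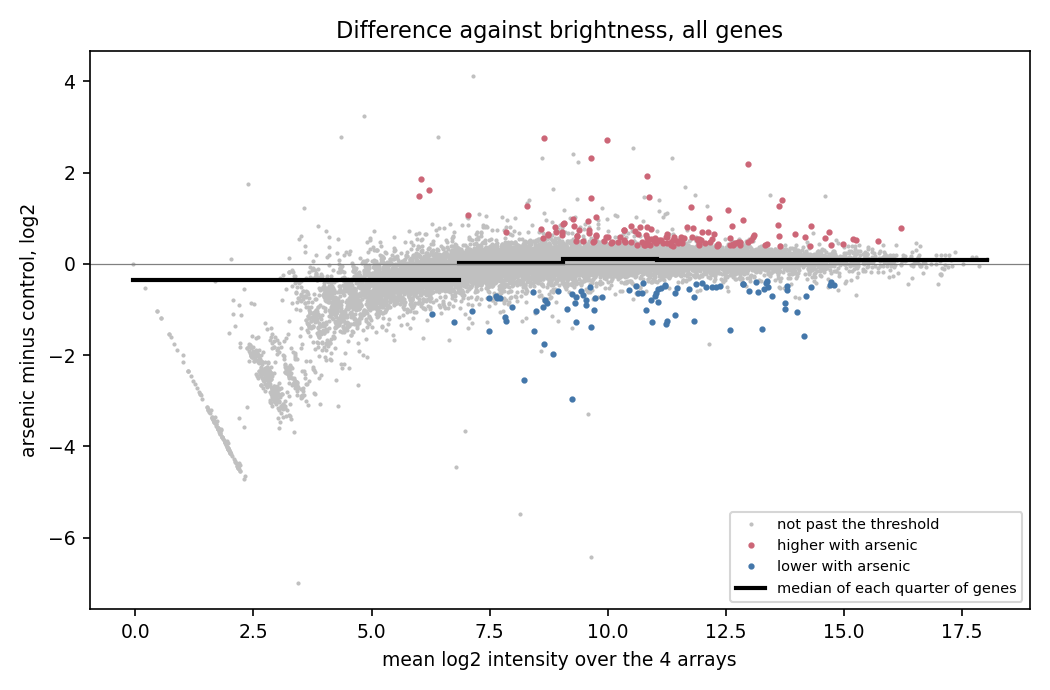
Log2 difference between the arsenic and control means (vertical axis) against the mean log2 intensity over the 4 arrays (horizontal axis), 1 point per gene, with the 143 genes higher and 88 lower with arsenic coloured. Black lines give the median difference in each 25% of genes by brightness, -0.36 in the dimmest and 0.10 in the brightest.

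Brightness moved with the groups. The median difference was -0.36 (log2) in the dimmest 25% of genes, 0.012 in the next 25%, and 0.10 in each of the brighter bins of 25%, against 0.021 over all genes. Values at or below 0 made up 0.0870% and 0.0227% of probes on the control arrays and 1.12% and 2.99% on the arsenic arrays. The median of each gene list was therefore also set against 10000 random lists of the same size and brightness. At unadjusted p under 0.05, limma counted 4760 genes, 24.9% of those tested. The groups did not overlap in 58.7% of genes, where chance gives 33.3% for arrays that differ in nothing by group. A shift in scale or brightness between the groups separates genes too. Neither this share nor the 24.9% therefore measures a response to arsenic. For a single gene, 2 against 2 arrays allow an exact two-sided permutation p of 0.333 at the lowest.

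Among the 12 largest rises, Egr1, a zinc finger transcription factor of the early response, rose 2.40-fold (log2 difference 1.26 ± 0.056, SE) and Zfp36, which destabilises cytokine mRNAs, rose 2.38-fold (1.25 ± 0.045). Fos rose from a log2 intensity of 11.88 ± 0.024 to 14.08 ± 0.13 (SD, n = 2 arrays per group), and Fosb from 8.49 ± 0.037 to 10.81 ± 0.28. Socs3, an inhibitor of cytokine receptor signalling, rose 2.78-fold (1.47 ± 0.13, SE). Rnu2-10, a gene for the U2 spliceosomal RNA, rose 3.79-fold, and Malat1, a long RNA of nuclear speckles, rose 2.26-fold. Tcap, a sarcomere protein that binds titin, rose 2.74-fold, Ttr, a carrier of thyroxine, 2.63-fold, and Klf15, a transcription factor induced by glucocorticoids, 2.05-fold. The limma adjusted p of these 12 genes lay between 0.00287 for Rn7sk and 0.0416 for Malat1 and Klf15.

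Among the 12 largest falls, Myh2 went from 10.73 ± 0.013 to 7.77 ± 0.018 (log2 intensity, SD, n = 2 arrays per group) and Ankrd1 from 9.51 ± 0.0029 to 6.96 ± 0.031. The atrial myosin light chains Myl7 and Myl4 were 3.97-fold and 2.97-fold lower, and Actc1, the cardiac actin, was 2.68-fold lower. Cxcl9, a chemokine induced by interferon gamma, was 3.40-fold lower, while its other probe differed by -0.50 (log2). Matrix genes in this set were Col8a2, a chain of collagen VIII, 2.40-fold lower, and Mfap4, a protein of elastic microfibrils, 2.41-fold lower. Msln, mesothelin of the mesothelial surface, was 2.49-fold lower and Itgbl1, an integrin-like protein, 2.42-fold lower. Ptprz1, a receptor tyrosine phosphatase, was 2.77-fold lower, and Npy6r, a neuropeptide Y receptor gene, 2.73-fold lower. Their limma adjusted p ran from 0.00287 for Myh2 to 0.0244 for Npy6r and Itgbl1. These 24 genes kept their direction under each alternative that held them, though most alternatives could not turn it. As their groups do not overlap, leaving out 1 array cannot turn the sign. Filters, fits, the replicate block and thresholds leave a gene's difference unchanged. The offset keeps the order of the arrays and could not turn it either. The mean of probes could bear on Cxcl9 alone, as the others had 1 probe, and did not turn it. Scaling could have turned a sign and did not, though the smallest of these differences was 1.03 (log2, Klf15).

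**Figure D2:**
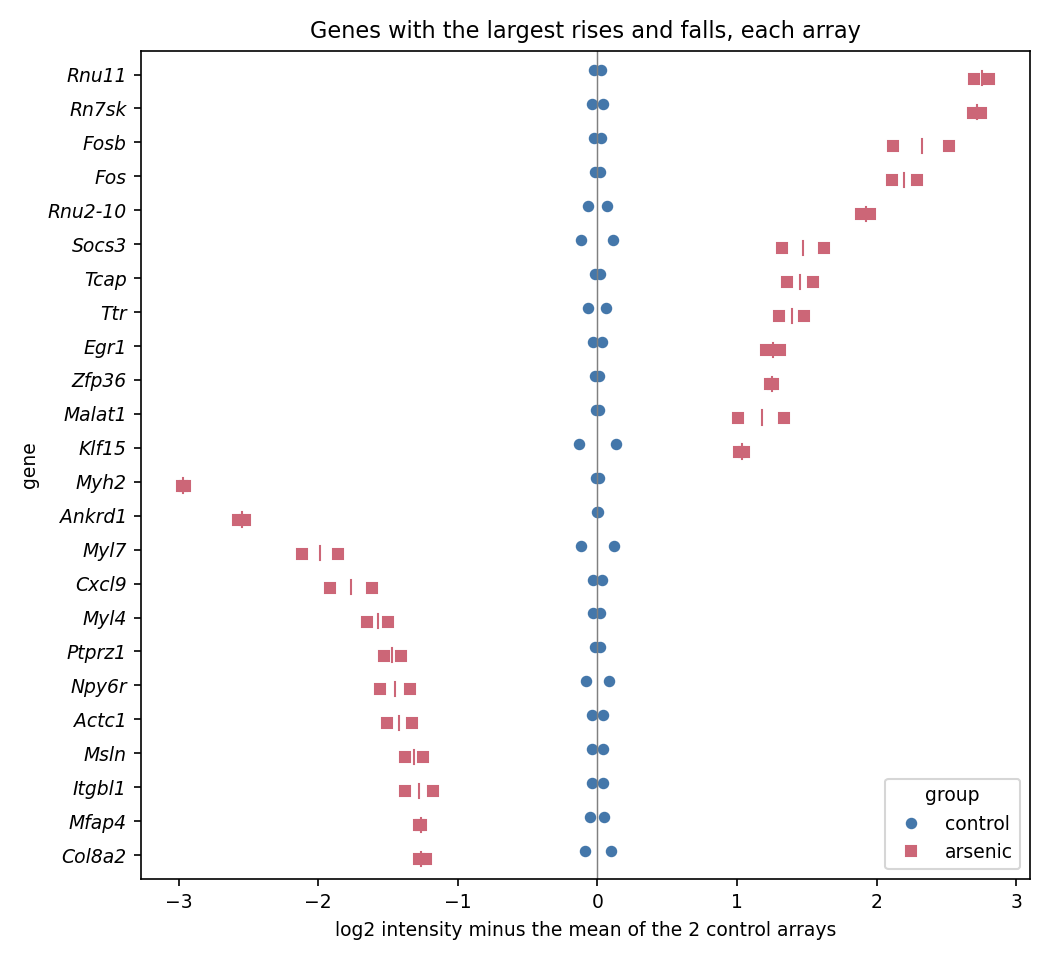
Each array's log2 intensity minus the mean of the 2 control arrays (horizontal axis) for the 12 genes with the largest rises and the 12 with the largest falls (vertical axis). Circles are control arrays, squares arsenic arrays and vertical ticks the arsenic mean, from 2.76 for Rnu11 to -2.97 for Myh2, and the arrays of the groups do not overlap for any gene drawn.

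Of 47 gene lists fixed in advance, 46 had at least 5 measured members and were tested with camera, and 20 passed an adjusted p under 0.05, 10 up and 10 down. With an estimated correlation between genes 0 lists passed, the lowest adjusted p being 0.492. That version rests on 2 residual degrees of freedom and could hardly pass any of 46 lists. The estimated correlation was 0.015 for NRF2 targets, near the preset 0.01, -0.080 for neutrophils and 0.37 for glucocorticoid-responsive genes. All 3 lists had the same 0.492, so this value does not tell whether correlation between genes undid a call. The test fry, which asks whether a list's genes move one way on balance, passed 7 lists: NRF2 targets, neutrophils, skeletal muscle, glucocorticoid-responsive genes, endothelium, immediate early genes and luminal urothelium. Of the 20 lists, 12 had medians outside the central 95% of random lists matched on brightness, and 8 lay inside.

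NRF2 targets and glutathione or thioredoxin enzymes, which detoxify electrophiles and oxidants, passed camera upward. Of 32 measured members, 2 rose over all genes and 21 rose adjusted over the list alone, 0 fell on either count, and 29 had higher means. Gpx2, a glutathione peroxidase, rose 1.50-fold and Gsta3, a glutathione transferase, 1.49-fold. Gclm, a subunit of glutamate-cysteine ligase, was at 1.35-fold (adjusted p = 0.0516 by limma), Hmox1, heme oxygenase, at 1.47-fold (0.0529), Nqo1 at 1.20-fold (0.136) and Gclc at 1.14-fold (0.416). The list median was 0.25 (log2), above the matched range of 0.022 to 0.14, with a camera adjusted p = 3.49e-07, and adjusted p = 0.492 with an estimated correlation. The median was 0.16 after quantile normalization or cyclic loess.

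The lists of metallothioneins and heat shock proteins did not pass. Of 10 measured metallothioneins and zinc transporters, 0 changed over all genes or adjusted over the list alone. Mt1 differed by 0.16 ± 0.050 (log2, SE) and Mt2 by -0.12 ± 0.044, and the list median was 0.12 (camera adjusted p = 0.973), while its mean was -0.044. That median was -0.18 without control replicate 2 and -0.063 without arsenic replicate 1. Of 17 heat shock proteins, 0 changed over all genes, and adjusted over the list alone Hspa1a at 1.28-fold and Chordc1 at 1.17-fold were higher and Dnajb1 at -0.20 (log2) and Hspb1 at -0.20 lower. The heat shock median was 0.069 (camera adjusted p = 0.454) and turned to -0.015 with quantile normalization and -0.019 with cyclic loess. In the list of arsenic metabolism and transport, Abcb1a, an efflux pump, rose 1.67-fold, the only one of 18 members past the test over all genes, with 4 up and 0 down adjusted over the list alone. As3mt, the methyltransferase of arsenic, differed by -0.080 ± 0.055 (log2, SE; limma adjusted p = 0.407). That list's median was 0.17 (matched range -0.022 to 0.15; camera adjusted p = 0.00661, and adjusted p = 0.492 with an estimated correlation). It was 0.11 with quantile normalization or cyclic loess. Its call was lost without control replicate 1 (0.0535) and without the dimmest 25% (0.0693) or 50% of genes (0.167), in a range of 0.00471 to 0.167 over camera's other settings.

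The lists of immediate early genes and glucocorticoid-responsive genes share Dusp1. Of 23 immediate early genes 7 rose and 1 fell, and adjusted over the list alone 8 rose and 3 fell, while 13 had higher and 10 lower means. Besides Fos, Fosb, Egr1 and Zfp36, the risen members were Dusp1, a phosphatase of MAP kinases, at 1.77-fold, and, named after their values were seen, Junb at 1.95-fold and Klf4 at 1.43-fold. Nr4a1, also named after its value was seen, fell, by 0.58 on the log2 scale. The median of the list was 0.13, inside the matched range (-0.0034 to 0.14; camera adjusted p = 0.0448, and adjusted p = 0.492 with an estimated correlation). It was 0.085 with median centring, 0.036 with quantile normalization, 0.035 with cyclic loess and 0.19 without the dimmest 25% of genes. Its call was lost without control replicate 1 (0.0689), without control replicate 2 (0.135) and without the dimmest 25% (0.128) or 50% of genes (0.297), the range over camera's other settings being 0.00558 to 0.297. The replicate block ended the immediate early call too (camera adjusted p = 0.0571). Of 15 glucocorticoid-responsive genes 5 rose and 0 fell, and adjusted over the list alone 10 rose and 2 fell. Fkbp5, a chaperone of steroid receptors, rose 1.78-fold, Zbtb16 1.57-fold, Klf9 1.51-fold and Tsc22d3, named after its value was seen, 1.31-fold. Their list median was 0.31 (matched range -0.0035 to 0.17; camera adjusted p = 0.000233, and adjusted p = 0.492 with an estimated correlation). Of 18 circadian clock genes, Tef rose 1.35-fold, with 9 up and 2 down adjusted over the list alone. Among the others, Dbp was at 1.33-fold and Nr1d2 at 1.51-fold, and the clock median was 0.21 (matched range -0.021 to 0.15; camera adjusted p = 0.0183, and adjusted p = 0.528 with an estimated correlation). The clock call was lost without control replicate 1 (0.0785) and without the dimmest 25% (0.111) or 50% of genes (0.278), with 0.00340 as the lowest value over camera's other settings.

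Of 20 skeletal muscle genes 4 fell and 0 rose, and adjusted over the list alone 7 fell and 0 rose. Next to Myh2, Tnnt3, a fast troponin T, was 2.02-fold lower, Acta1, the skeletal actin, 1.46-fold lower and Eno3, the muscle enolase, 1.42-fold lower. Their median was -0.45 (matched range -0.15 to 0.077; camera adjusted p = 0.000232, and adjusted p = 0.492 with an estimated correlation). It was -0.22 with quantile normalization, -0.19 with cyclic loess and -0.29 with an offset of 32. Of 19 smooth muscle genes 2 fell and 0 rose, and adjusted over the list alone 7 fell and 1 rose. Cnn1, calponin, was 1.49-fold lower and Tagln, transgelin, 1.40-fold lower. With the probes used, Synm and Pgm5 differed by -0.42 and -0.32 (log2) and did not pass. The other, dimmer probes of Synm differed by -0.56 and -0.55, and that of Pgm5 by -0.55. The smooth muscle median was -0.11, where matched lists lay between 0.018 and 0.16 (camera adjusted p = 0.000352, and adjusted p = 0.492 with an estimated correlation), and -0.21 with quantile normalization or cyclic loess.

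Of 44 collagen genes, Col8a2 and Col3a1, the chain of fibrillar collagen III, fell and 0 rose, and adjusted over the list alone 7 fell and 1 rose. Col3a1 was 1.56-fold lower, and Col8a1 and Col1a2 differed by -0.46 and -0.36 (log2). The collagen median was -0.21 (matched range -0.081 to 0.056; camera adjusted p = 0.000196, and adjusted p = 0.492 with an estimated correlation). It was -0.086 with quantile normalization or cyclic loess, -0.061 and -0.13 without the dimmest 25% and 50% of genes, and -0.14 without arsenic replicate 2. Of 25 fibroblast and extracellular matrix genes 2 rose and 4 fell, and adjusted over the list alone 5 rose and 7 fell. Pi16, a marker of adventitial fibroblasts, was 1.63-fold lower, and Dpt, dermatopontin, 1.41-fold lower, while Pdgfrb, the platelet-derived growth factor receptor of pericytes and fibroblasts, rose 1.50-fold. Sparc also fell, by 0.39 on the log2 scale, and Tnc rose by 0.40, both named after their values were seen. The fibroblast median was -0.16 (camera adjusted p = 0.116), below the matched range of 0.019 to 0.15, and ran from -0.23 to -0.066 over the other settings. The list passed camera with quantile normalization (0.0136), cyclic loess (0.0198) and the replicate block (0.0490). It also passed without the dimmest 25% (0.00676) or 50% of genes (0.000147), in a range of 0.000147 to 0.508.

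Of 12 neutrophil genes 2 fell and 0 rose, and adjusted over the list alone 3 fell and 0 rose. Il1r2, a decoy receptor of interleukin 1, was 1.58-fold lower and S100a8, a calcium-binding protein of granulocytes, 1.47-fold lower, while S100a9 differed by -1.41 ± 0.18 (log2, SE; limma adjusted p = 0.0529). The neutrophil median was -0.43 (matched range -0.28 to 0.053; camera adjusted p = 0.000107, and adjusted p = 0.492 with an estimated correlation), -0.24 with quantile normalization or cyclic loess, and -0.20 without the dimmest 25% of genes. Of 13 B and plasma cell genes, Jchain, the joining chain of polymeric antibodies, was 1.92-fold lower and the other members did not pass, with 2 down and 0 up adjusted over the list alone. Their median was -0.26 (matched range -0.15 to 0.12; camera adjusted p = 0.0170, and adjusted p = 0.492 with an estimated correlation), lost without control replicate 1 (0.103) or arsenic replicate 2 (0.0517; range over camera's other settings 0.00514 to 0.103). That median was -0.073 with quantile normalization, -0.074 with cyclic loess, -0.054 without the dimmest 25% of genes and -0.11 with an offset of 32. Without 1 array it ran from -0.42 (without arsenic replicate 1) to -0.10 (without control replicate 1). Of 18 endothelial genes 0 changed over all genes and 8 rose adjusted over the list alone, among them Pecam1 at 1.50-fold, Cldn5 at 1.42-fold and Tek at 1.39-fold. The endothelial median was 0.26 (matched range -0.0089 to 0.15; camera adjusted p = 0.00117, and adjusted p = 0.492 with an estimated correlation). Of 9 erythroid genes 0 changed, 1 fell adjusted over the list alone (Hbb-b1, at -0.38 on the log2 scale), and the median was -0.13, inside the matched range (-0.19 to 0.13; camera adjusted p = 0.0499, and adjusted p = 0.492 with an estimated correlation). The erythroid median was -0.049 with quantile normalization and ran to -0.35 without arsenic replicate 1. With the replicate block the list did not pass (camera adjusted p = 0.0525). That call ended with quantile normalization (0.0894), median centring (0.0858), cyclic loess (0.0983), an offset of 32 (0.0530) and the scale factors undone (0.0624), and without control replicate 1 (0.142), arsenic replicate 1 (0.0756) or arsenic replicate 2 (0.155), in a range of 0.0150 to 0.155.

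Urothelial markers did not pass as lists. Of 21 luminal urothelium genes 0 changed over all genes, and 6 rose and 2 fell adjusted over the list alone. The transcription factors Foxa1 and Elf3 were at 1.29-fold and 1.21-fold, the tight junction gene Cldn8 differed by -0.26 (log2), and Upk2, a uroplakin, by 0.012 ± 0.055 (SE). The luminal median was 0.050 (matched range 0.0065 to 0.15; camera adjusted p = 0.350, and fry adjusted p = 0.0160), and it became -0.011 with quantile normalization and -0.013 with cyclic loess. Of 15 basal urothelium genes, Cd44, a hyaluronan receptor, rose 1.55-fold and Trp63, a transcription factor of basal cells, 1.46-fold, the same 2 genes adjusted over the list alone, and 0 fell. Krt5 differed by 0.14 ± 0.071 (log2, SE), and the basal median was 0.064 (matched range -0.0060 to 0.17; camera adjusted p = 0.296), or -0.016 with quantile normalization and -0.027 with cyclic loess.

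Of 30 measured cell cycle and mitosis genes, Ccna2, cyclin A2, was 2.78-fold lower and no other member passed, with 5 down and 0 up adjusted over the list alone. Top2a and Tpx2 differed by -0.78 and -1.24 (log2), and Mki67 by 0.024 ± 0.073 (SE), while its second, dimmer probe gave -0.68. The list median was -0.25 (matched range -0.12 to 0.057; camera adjusted p = 0.000116, and adjusted p = 0.492 with an estimated correlation). The median was -0.14 with cyclic loess, -0.16 without control replicate 2 and -0.091 without the dimmest 25% of genes. Without the dimmest 50% of genes the median was 0.024 and the call was lost (camera adjusted p = 0.138; lowest over camera's other settings 9.10e-05).

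**Figure D3:**
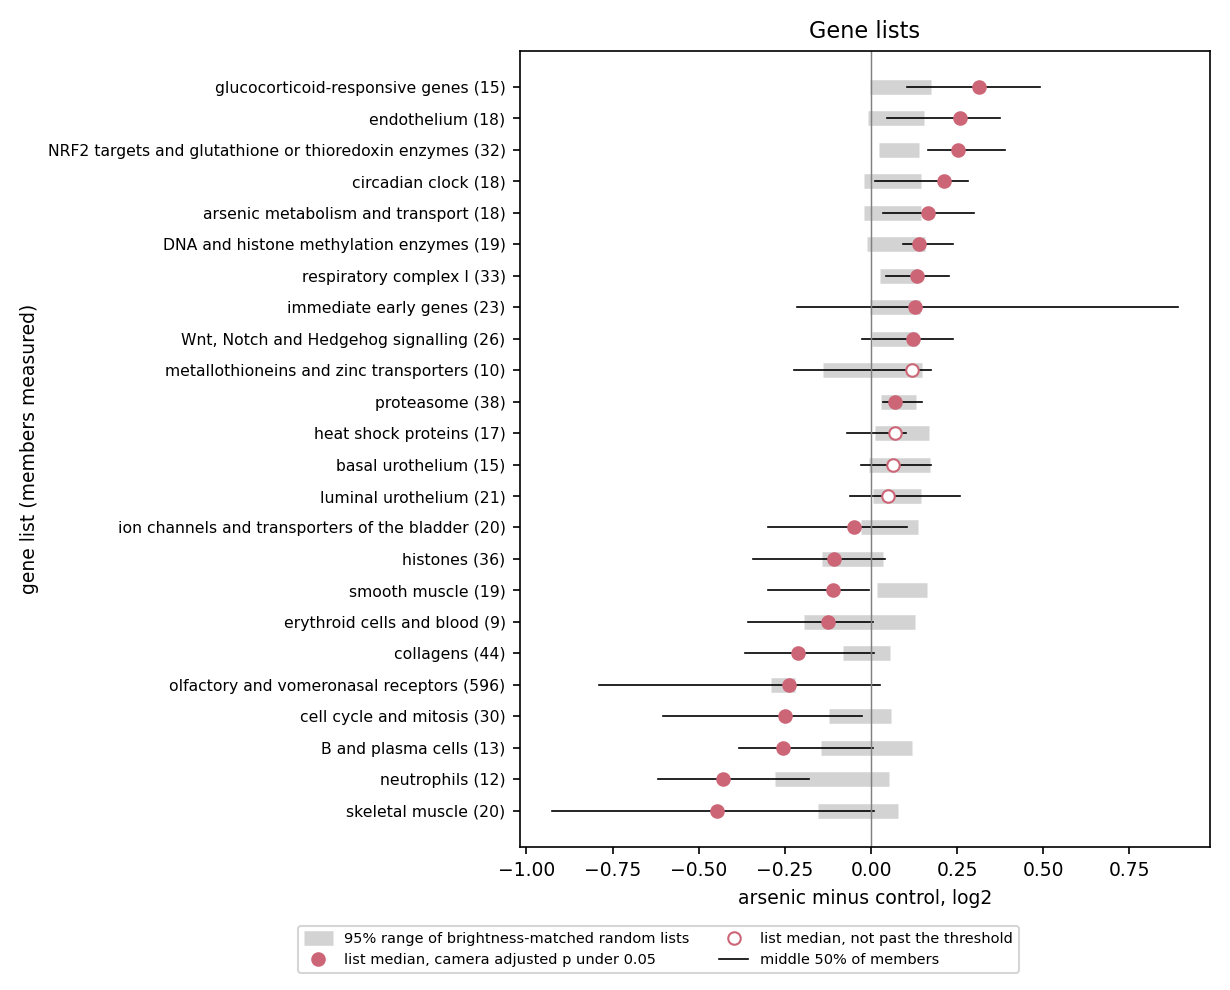
Median log2 difference, arsenic minus control (horizontal axis), of the 20 gene lists past the camera test (filled circles) and of 4 lists of main interest that were not (open circles), with the members measured in brackets. Grey bars span the central 95% of 10000 random lists matched on brightness and thin lines the middle 50% of members; medians run from -0.45 for skeletal muscle to 0.31 for glucocorticoid-responsive genes, and those of heat shock proteins, the proteasome and both urothelium lists turn negative with quantile normalization or cyclic loess.

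Other lists passed camera, each with an adjusted p = 0.492 with an estimated correlation. Respiratory complex I had a median of 0.13 over 33 members, 0 of which passed over all genes and 9 rose adjusted over the list alone (camera adjusted p = 0.000111, and 0.0659 without the dimmest 50% of genes, with 3.59e-06 as the lowest), near the top of the matched range of 0.027 to 0.14. That median was 0.060 with quantile normalization and 0.061 with cyclic loess. DNA and histone methylation enzymes had a median of 0.14 over 19 members, inside the matched range of -0.012 to 0.16, of which Kmt2a, a histone methyltransferase, rose 1.41-fold, with 5 up and 1 down adjusted over the list alone (0.00429, and 0.167 without the dimmest 50% of genes, with 0.00120 as the lowest). Proteasome genes had a median of 0.071 over 38 members, inside the matched range of 0.028 to 0.13, with Psmb7 up 1.50-fold and 4 up and 1 down adjusted over the list alone (0.0183). That median was -0.019 with cyclic loess and 0.00034 with quantile normalization, and the call was lost (0.773 and 0.645). It was also lost with median centring (0.0764) and without the dimmest 25% (0.141) or 50% of genes (0.294), control replicate 1 (0.0942) or arsenic replicate 2 (0.127), in a range of 0.00217 to 0.773. Wnt, Notch and Hedgehog genes had a median of 0.12, inside the matched range of 0.0028 to 0.13, with 0 of 26 past the test and 7 up adjusted over the list alone, Wnt5a at 1.29-fold among them (0.0499). That median was 0.072 with cyclic loess, 0.080 with median centring and 0.21 without arsenic replicate 2. Leaving out any of the 4 arrays ended that call (0.0542 to 0.121), it passed in 6 of 16 other settings, and its range over camera's other settings was 0.0144 to 0.404. Ion channels and transporters of the bladder had a median of -0.049 over 20 members, of which Trpv2, a cation channel, was 1.40-fold lower, with 4 down adjusted over the list alone (0.0454). That median was -0.22 without arsenic replicate 1 and -0.0043 without the dimmest 25% of genes. With the replicate block this list did not pass (camera adjusted p = 0.0897). The call was lost with median centring (0.0576), with the scale factors undone (0.0732) and without control replicate 1 (0.117), arsenic replicate 1 (0.0632) or arsenic replicate 2 (0.111), in a range of 0.00174 to 0.117. Histones had a median of -0.11, inside the matched range of -0.14 to 0.034, with 0 of 36 past the test and 1 down, H2ac23 at -0.40 (log2), adjusted over the list alone (0.0167). That call was lost with quantile normalization (0.184, median -0.018), cyclic loess (0.211) and without arsenic replicate 1 (0.0756), in a range of 0.00279 to 0.211. Olfactory and vomeronasal receptors had a median of -0.24 with 0 of 596 past either count (4.46e-07), inside the matched range of -0.29 to -0.22. Their median was -0.0023 with quantile normalization, -0.013 with cyclic loess and 0.085 without the dimmest 50% of genes, and the call was lost (0.839, 0.579 and 0.638; lowest over camera's other settings 6.35e-08).

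The remaining lists did not pass camera with the settings used for the 20 lists, though single members changed. In xenobiotic metabolism the cytochrome P450 genes Cyp1a1, Cyp2e1 and Cyp2f2 were 1.80-fold, 1.51-fold and 1.43-fold lower, 0 of 16 rose, and adjusted over the list alone 4 rose and 5 fell (median 0.12, camera adjusted p = 0.942). Pmaip1, a p53 target that promotes apoptosis, was 1.72-fold lower, 1 of 18 in its list (median 0.056, 0.973), while Cdkn1a was at 1.22-fold (limma adjusted p = 0.0703). Krt4 was 1.62-fold lower, 1 of 21 squamous genes (median -0.065, 0.315) and 1 of 53 keratins (-0.019, 0.604). Mmp10, a matrix metalloproteinase, rose from a dim log2 intensity of 5.26 to 6.75, and Ccn2, a matricellular growth factor, was 2.09-fold lower in the list of matrix proteases and migration, where 2 rose and 3 fell adjusted over the list alone (median -0.0039, 0.762). Nfkbia rose 1.34-fold and S100a8 fell among 25 inflammatory genes (-0.033, 0.210), Cxcl9 fell among 21 interferon-stimulated genes (-0.041, 0.153) and Cd3d was 1.53-fold lower among 16 T and NK cell genes (-0.097, 0.0830). Pck1 was 2.02-fold lower among 18 adipocyte genes (-0.055, 0.315) and Sprr2f rose 1.60-fold among 18 oestrogen-responsive genes (-0.11, 0.210). No member passed over all genes in the lists of ribosomal proteins (median 0.079, 0.0806), macrophages and monocytes (-0.060, 0.119), DNA repair (0.060, 0.153), mast cells and eosinophils (-0.15, 0.381) or EGFR, FGFR and MAPK signalling (-0.042, 0.393). The same held for cholesterol synthesis (-0.063, 0.568), glycolysis and hypoxia (0.075, 0.568), nerve and Schwann cells (0.070, 0.588), antigen presentation (0.0034, 0.762), fatty acid oxidation (0.012, 0.762) and the unfolded protein and ATF4 response (0.044, 0.762). Median, mean and camera direction differed in sign for metallothioneins, luminal and basal urothelium, ribosomal proteins, xenobiotic metabolism, p53 targets, matrix proteases, antigen presentation and fatty acid oxidation.

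Some of these lists passed camera under other settings. Macrophages and monocytes, below the matched range of -0.010 to 0.15, passed with quantile normalization (median -0.14, adjusted p = 0.00527), cyclic loess (-0.15, 0.00656) and without the dimmest 25% (0.0130) or 50% of genes (0.0107), in a range of 0.00527 to 0.307. Interferon-stimulated genes, below the matched range of -0.015 to 0.15, passed with quantile normalization (-0.082, 0.0226), cyclic loess (-0.079, 0.0253) and without the dimmest 25% of genes (0.0353), in a range of 0.0226 to 0.264. Without the dimmest 25% of genes, T and NK cells (0.00515, range up to 0.418) and inflammatory genes (0.0353, up to 0.404) passed downward. Cholesterol synthesis passed downward with cyclic loess (0.0420) and without the dimmest 50% of genes (0.0459, range up to 0.782), and adipocytes without the dimmest 50% (0.0459, up to 0.574). With all probes tested, DNA repair (0.0398, range up to 0.570) and ribosomal proteins (0.0429, up to 0.567) passed upward. With an estimated correlation the adjusted p of each of these lists was at least 0.492.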

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

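The comparison by gene left out the 4547 probes without a gene name, and some of these differed between the groups. Tested together with all 26423 probes by limma, 13 of them passed a Benjamini-Hochberg adjusted p under 0.05, 6 higher and 7 lower with arsenic, and 700 had an unadjusted p under 0.05. That was 0.286% of unnamed probes, against 0.649% of probes with a gene name. What these probes measure was not analysed here.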

How the results depend on the processing

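Cyclic loess and undoing the scale factors were chosen after the data were seen, and the causes of the differences below were not tested. Against 231 genes changed by arsenic (143 higher, 88 lower), median centring gave 85 (34, 51), of which 84 were among the 231, and quantile normalization 178 (61, 117), 141 shared. Dropping the dimmest 25% of genes gave 533 (376, 157), dropping 50% gave 961 (763, 198), with fewer genes tested, and an offset of 32 gave 375 (245, 130). Testing all probes gave 155 (87 higher, 68 lower) and the mean of a gene's probes 268 (166, 102). Limma without a trend called 59 (6, 53), 17 of them shared, and with robust estimation 888 (631, 257). At an adjusted p under 0.10 the count was 1723 (1259, 464), and at an unadjusted p under 0.05 with at least 2-fold it was 361 (22, 339). Cyclic loess gave 225 (85, 140), 167 shared, and undoing the scale factors 50 (23, 27), all 50 shared. Without 1 array the counts ran from 0 to 219 (0 to 79 higher, 0 to 140 lower): 0 without control replicate 1 or 2, 219 without arsenic replicate 1 and 38 without arsenic replicate 2, the lone sample being assumed to vary like the other group. The replicate numbers share no stated origin. With the number as a block, 2221 genes were called (1706, 515), and deviations from the group means correlated across genes at 0.20 between same-numbered arrays, and at 0.41 over the brighter 50% of genes. The block ended the camera calls of erythroid cells (adjusted p = 0.0525), immediate early genes (0.0571) and ion channels (0.0897), and fibroblast genes passed (0.0490). The gene lists past camera numbered 20, and 12 without the dimmest 50% of genes, 0 with an estimated correlation, 7 with fry, 18 with the block, and 12 to 18 without 1 array (12 without control replicate 1, 15 without arsenic replicate 2). The NRF2 median of 0.25 passed camera under each scaling, filter, probe rule and left-out array, but not with an estimated correlation (adjusted p = 0.492). The cell cycle median of -0.25 did not pass with an estimated correlation (0.492) or fry (0.0781), nor, at 0.024, without the dimmest 50% of genes. The luminal urothelium median of 0.050 passed with fry (0.0160), and camera turned to down without the dimmest 50%, at a median of 0.050. Camera's direction also turned for heat shock proteins with quantile normalization (median -0.015), cyclic loess (-0.019) and without the dimmest 25% or 50% (0.069 in both). It turned for metallothioneins without the dimmest 50% (0.17), with the mean of probes (0.054), without control replicate 2 (-0.18) and without arsenic replicate 1 (-0.063), in a range of -0.18 to 0.12 without 1 array. None of these turned values passed. Mki67 changed sign with median centring (-0.018), quantile normalization (-0.080), the mean of probes (-0.33), cyclic loess (-0.078), and without control replicate 1 (-0.012) or arsenic replicate 2 (-0.053), up to 0.10 without arsenic replicate 1. Upk2 did so with median centring (-0.030), quantile normalization (-0.067), cyclic loess (-0.057), and without control replicate 2 (-0.028) or arsenic replicate 1 (-0.00037), up to 0.053 without control replicate 1. Of 82 named genes past the threshold, 0 changed sign under any alternative run, 70 stayed past it with quantile normalization, 49 with median centring, 33 with the scale factors undone, 13 without a trend, 53 without arsenic replicate 1, 31 without arsenic replicate 2 and 0 without either control array. Filters, fits, the block and thresholds leave a gene's difference unchanged and could not change a sign. Leaving out 1 array or adding an offset could not either where the groups do not overlap, nor could the mean of probes for genes with 1 probe. Without the dimmest 50% of genes, 68 of these named genes were in the fit. Low signal over background limits dim genes, whose standard errors were widest.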

Other observations

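Genes in this paragraph were chosen after their values were seen. All 4 spliceosomal and 7SK small nuclear RNAs on the array rose, Rnu12, of the minor spliceosome, by 1.86 ± 0.17 (log2, SE) from a dim control log2 intensity of 5.12, next to Rnu11, Rnu2-10 and Rn7sk, with a median of 2.32. Of 64 small nucleolar and Cajal body RNAs 2 rose, Snord13 at 1.74-fold and Snord118 at 1.68-fold, with a class median of -0.071, and of 222 microRNA genes 0 changed by limma. Cyclins D1 and D2 fell, Ccnd1 being 1.98-fold and Ccnd2 1.34-fold lower. Outside the lists, Tgfb3, a growth factor that induces matrix, was 1.78-fold lower, Fmod, a collagen-binding proteoglycan, 1.72-fold lower and Serpinh1, a collagen chaperone, 1.38-fold lower. Muscle genes did not all go one way, since Mybpc1, a slow myosin-binding protein, rose 2.42-fold and Trdn, triadin of the sarcoplasmic reticulum, 1.68-fold, as Tcap did. At 2.42-fold, Mybpc1 was not among the 12 largest rises, so it missed the limits set there on threshold, overlap or brightness. The plasma protein genes Rbp4 and Fetub rose 1.79-fold and 1.87-fold, and Id3 and Id1, inhibitors of basic helix-loop-helix factors, 1.78-fold and 1.45-fold.

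In 30 genes brighter than the median, 1 array lay at least 2 (log2) from the median of the other 3, which were within 1 of each other. In 29 of these the odd array was lower, 18 of them on control replicate 1, 5 on control replicate 2 and 6 on arsenic replicate 2. On arsenic replicate 2, Top2b and Jund were deposited at or below 0 and set to the floor, against medians of 12.88 and 10.86 on the other arrays. On control replicate 1, Tsfm read 6.75 against 11.81. None of the 30 passed the limma test; these examples and the limits were chosen after the values were seen.

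The tests for the share of urothelium, for handling and for YAP and TAZ targets were chosen after the results were seen. The fall of olfactory and vomeronasal receptor genes, whose median log2 intensity was 5.96 against 9.06 over all genes, had a median of -0.24. Among random lists matched on brightness that median stood at the 88.98th percentile, as a trend with brightness between the arrays would give. The fall is therefore consistent with that trend, and with quantile normalization the median was -0.0023. No biological explanation was tested.

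The median of NRF2 targets and glutathione or thioredoxin genes stood at the 100th percentile of lists matched on brightness, above what the brightness trend gives, while 9.22% of matched lists held as many risen genes as its 2. A higher share of urothelium in the arsenic samples could also raise them. The NRF2 median exceeded the luminal urothelium median by 0.202 (95% bootstrap interval -0.011 to 0.312), an interval that holds 0 and does not exclude such a share. The bootstrap resampled the genes of each list, so the interval measures spread between genes and not between arrays or mice. The luminal and basal medians stood at percentiles 22.21 and 30.71 of matched lists, so neither list lay above its matched range, as a higher share would need. The luminal list did pass fry (adjusted p = 0.0160). Medians of smooth muscle (-0.11), skeletal muscle (-0.45), collagens (-0.21) and fibroblast genes (-0.16) lay below their matched ranges, and that of endothelium (0.26) above. Whether the shares of these tissues differed between the groups was not tested. A response to arsenic may be the source, but with the control and arsenic mice as the only groups, other differences between them cannot be separated from it.

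The count of 7 risen immediate early genes went beyond the brightness trend: random lists matched on brightness held as many with a permutation p = 1e-04 over gene lists, the smallest that 10000 draws can give. The list median of 0.13 lay inside the matched range (-0.0034 to 0.14), and 13 members had higher and 10 lower means. Handling or time of dissection could raise these genes quickly, and glucocorticoid-responsive genes, which respond to stress, stood at the 100th percentile of matched lists. Circadian clock genes, which bear on the time of dissection, stood at the 99.97th percentile, with 13 higher and 5 lower means. No record of dissection was used here, so handling, time of dissection and arsenic cannot be told apart. Of the 3 ways to split 4 arrays into pairs, the real one called 231 genes. The highest other, replicate 1 against replicate 2, called 54, and 3 splits are too few for a share under 0.05. Each other split mixes control and arsenic arrays, which widens its spread within groups, so its count is no measure of chance for the 231.

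A hypothesis was that Ankrd1, Ccn2 and Amotl2, targets of the coactivators YAP and TAZ, fell through lower transcription of YAP and TAZ targets. Amotl2 was 1.46-fold lower. The median of the other 19 measured genes of a list of 22 such targets was 0.057, at the 23.15th percentile of matched lists, which neither bears out the hypothesis nor excludes it. In 37 genes of the brighter 50%, replicate 1 was at least 2-fold above replicate 2 in both groups, and in 0 genes did the groups go opposite ways. For Foxf2, picked after its values were seen, the log2 gap was 1.58 in the control and 1.54 in the arsenic group. Same-numbered arrays thus shared a difference of unstated origin, which the main fit counted as spread within the groups.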
